A study of Rattus norvegicus with 4 samples.

How the data were processed

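RNA was taken from RCG-12 rat astrocytes after 3 days at 33 °C or 39 °C and measured on 4 Affymetrix Rat Expression Array 230A arrays, 2 per temperature. Per the labels' protocols, total RNA was treated with DNase, copied into double-stranded cDNA by one-cycle synthesis and transcribed into biotin-labelled cRNA. Probe sets of this array type lie mostly near the 3′ end of transcripts. The authors deposited 1 table of probe set signals for the whole series, as intensities on a linear scale. The software that summarised the probes and scaled the arrays is not given in the sources used here. The values themselves have a mean of 500.1 on every array after 2% of probe sets at each end are trimmed, so the arrays had been scaled to a common level before deposit. Such scaling sets the average of each array equal and cannot show a change in total RNA per cell.

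The groups were taken from the titles of the samples, which name the permissive or nonpermissive temperature, without degrees, and end in a replicate number. The table holds 15923 probe sets. The 57 control probe sets were left out of the tests, and probe sets whose mean log2 signal over the 4 arrays lay below the 40th percentile (a signal of 83.9) were left out as dim, since the deposited table used here gives no detection call. That left 9520 of 15866. A rise from or a fall to a mean signal below that limit is given as a bound, the brighter mean divided by the limit. The bound holds for the means and leaves out the spread between arrays, so a single array may lie above the limit. Gene symbols came from the platform annotation, updated through Entrez gene IDs to the rat RefSeq gene table of assembly GRCr8. Of the probe sets listed there, 12789 have 1 symbol and 312 have several; the others are unnamed here. Of those with 1 symbol, 12754 matched by Entrez ID, 2 matched by accession and 33 kept the platform's symbol. No gene was named from a probe set with several symbols, and 1392 tested probe sets had no single gene, 421 of them changed. The array names no genome build, so no positions are given. A gene with several tested probe sets was represented by the brightest.

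Log2 signals were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with an intensity trend, 39 °C minus 33 °C, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The arrays were used as deposited. The rule set in advance was to do so where the array medians agreed within 10%, without stating how agreement is measured. The highest median was 10.3% above the lowest, while no array was more than 5.12% from their mean, so the rule did not settle the choice; the equal trimmed means decided it. Division of each array by its median was an alternative listed in advance.

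The 29 gene lists, the tests and the alternatives were fixed before the data were examined. A list with at least 5 tested genes was tested with camera at its preset correlation of 0.01, two-sided and adjusted over the 25 lists tested. With that correlation 11 lists passed, and with a correlation estimated from the 4 arrays 0 passed. The estimated version has only the residual degrees of freedom of 4 arrays, which leaves it little power. Its smallest unadjusted camera p was 0.0241, for p53 targets. A list that failed it is therefore not shown to have shifted through correlation between genes. Genes were chosen for naming by 3 rules set in advance: the 12 largest rises and 12 largest falls in fitted log2 change, from or to dim signals included, past the threshold without overlap of the arrays, leaving out symbols that start with LOC or RGD or end in predicted; 27 genes fixed by name; and, per list, up to 4 members with the smallest adjusted p, plus up to 2 against the majority in lists tied to the study's question. Ccna2, Hspa8, Hsp90aa1 and Actb are among the fixed names and are not analysed here by name, since the annotation matched no probe set to them alone. The beta-actin control probe sets are given with the reference genes. Counts of list members under each scaling and without each array, and bounds on folds from dim signals, were added after the data were seen.

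The steps were tested on simulated data drawn from the arrays' means and spread, with 200 probe sets changed, against 3161 called in the real data. Each simulated probe set varied independently of the others, with a spread smoothed over brightness. Of the changed probe sets that passed the filter on dim ones, 100% were recovered at log2 changes of -2 and 2, 95.5% at -1 and 96% at 1, and 8 of 190 calls were false (4.21%). When a shift of 0.5 was also added to the lysosome genes in that simulation, 3 of 25 lists were called. The 2 besides the lysosome list were given no shift as lists. Whether they held some of the 200 changed probe sets or lysosome genes was not checked. Simulations with no change at all were added after this had been seen: in 50 of them, 1 called a list, and at most 1 probe set was called. Without correlation between genes, these runs cannot show how often the list test calls correlated genes by chance. Alternatives were quantile normalization, division by the median, no filter on dim probe sets and filters at the 20th and 60th percentiles, an offset of 37.5 (the 25th percentile of signals) before the log2, eBayes without trend or with robust fitting, the replicate number as a block, each array left out in turn, and for the lists an estimated correlation, the fry rotation test and the mean of a gene's probe sets. With an array left out, the lone array of a temperature is assumed to vary like the pair of the other.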

Results

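Gene expression was measured in RCG-12 cells, an astrocyte line made from rat cortical glia by infection with a temperature-sensitive form of the SV40 large T antigen. Large T antigen is a viral protein that binds and inactivates p53 and the retinoblastoma protein family and so keeps cells dividing; the temperature-sensitive form works at the permissive temperature of 33 °C and is lost at the nonpermissive temperature of 39 °C. Cells were kept at either temperature for 3 days, and 2 arrays were measured at each. Each array gave a signal for 15923 probe sets, of which 9520 were bright enough to be tested, standing for 7002 named genes. The array mean after trimming 2% of the probe sets at each end was 500.1 on every array, and the medians ran from 158.7 to 175.1. Precision is limited by the number of arrays, and the labels do not say whether the arrays of one temperature came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

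The series was set up to find genes that go with growth arrest and differentiation when the large T antigen is switched off. Temperature and large T antigen changed together, so each difference given here is one between the 2 culture conditions. Levels are mean signals ± SD of n = 2 arrays, changes are log2 values at 39 °C minus 33 °C ± SE, and p-values are adjusted over all tested probe sets. A range beside the median of a gene list runs over 3 scalings (as deposited, each array divided by its median, quantile normalization) and the fits without 1 array, and is given where the median changed sign or moved by over 1.5 times.

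After 3 days at 39 °C the neuropeptide Y gene Npy, the cyclin-dependent kinase inhibitor gene Cdkn1a and the detoxifying epoxide hydrolase gene Ephx1 stood far above their levels at 33 °C, and the cold-inducible RNA-binding protein gene Rbm3 far below. Npy rose from 157 ± 19.2 to 9006 ± 603, a log2 change of 5.85 ± 0.12 (adjusted p = 6.47e-09). Rbm3 had a signal of 9734 ± 1362 at 33 °C and 491 ± 1.98 at 39 °C, a log2 change of -4.30 ± 0.12 (adjusted p = 2.87e-08). In all, 3161 of the 9520 probe sets changed (33.2%), 1692 of them higher and 1469 lower at 39 °C, and 669 changed by 2-fold or more, 458 up and 211 down. The changed probe sets stood for 1275 genes that were higher and 1133 that were lower. The 2 arrays at 33 °C correlated with r = 0.986 and those at 39 °C with r = 0.985 over tested probe sets (a correlation across probe sets, which are not independent replicates), against 0.929 to 0.936 between temperatures. The arrays of the temperatures did not overlap in 68.2% of tested probe sets, where chance alone gives 33.3%.

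The count and its split depended on single arrays and on the scaling. It was 2027 without replicate 1 at 33 °C, 1821 without replicate 1 at 39 °C and 1933 without replicate 2 at 39 °C. Dividing each array by its median lowered the median change by 0.11 on the log2 scale, to -0.10, and turned the split into 1316 higher and 2181 lower, with 350 and 307 at 2-fold or more. Changes of about that size therefore have no settled direction.

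**Figure D1:**
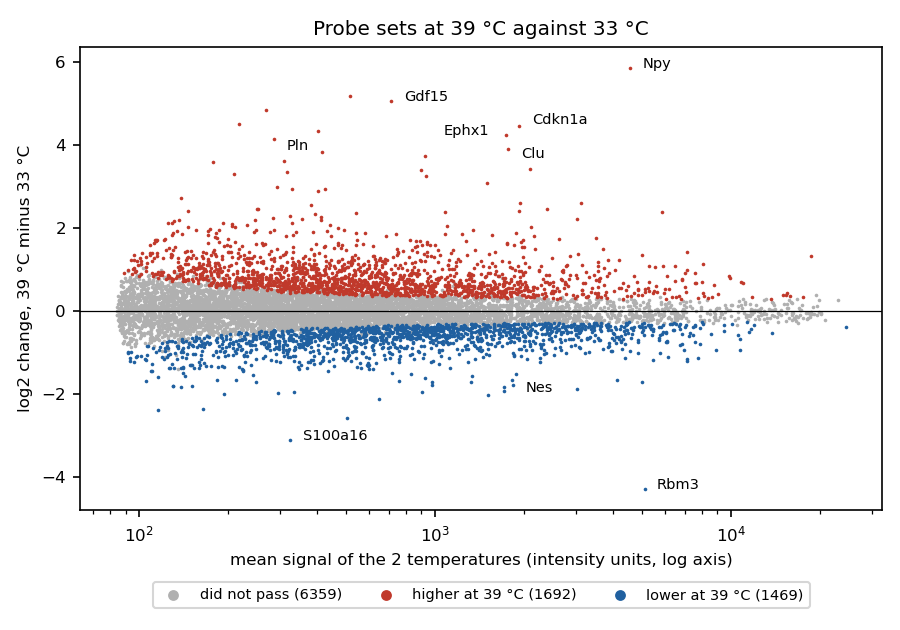
Log2 change at 39 °C against 33 °C (vertical axis) by mean signal in intensity units (horizontal log axis), 1 point per tested probe set. Red points are the 1692 probe sets higher at 39 °C, blue points the 1469 lower ones and grey points those that did not pass; Npy lies highest at 5.85 and Rbm3 lowest at -4.30.

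More p53 target genes rose than fell. Of 30 tested p53 target genes, 17 rose, 2 fell and 11 did not pass; adjusted over the list alone, 19 rose and 2 fell. The median log2 change was 0.88 (camera adjusted p = 3.2e-07; adjusted p = 0.238 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, went from 172 ± 51.9 to 3690 ± 49.7, a log2 change of 4.46 ± 0.18. Cyclin G1 (Ccng1) rose from 1899 ± 85.7 to 9852 ± 740, the DNA damage response gene Gadd45a rose 5.43-fold and the pleckstrin homology domain gene Phlda3 rose 4.02-fold. Mdm2, which encodes the ubiquitin ligase that targets p53, rose by a log2 change of 2.60 ± 0.15, and its dimmer probe set by 3.08 ± 0.22. The stress cytokine gene Gdf15 reached 1373 ± 182 at 39 °C from a signal at 33 °C that lay among the dim probe sets, so it rose at least 16.4-fold. Against this direction, the polo-like kinase gene Plk2 fell 1.79-fold and the phosphatase gene Dusp1 fell 1.48-fold.

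Among 11 tested genes of CDK inhibitors, D-type cyclins and pocket proteins, 3 rose, 1 fell and 7 did not pass, and the counts adjusted over the list alone were also 3 and 1. The risers were Cdkn1a, cyclin D2 (Ccnd2, log2 change 2.94 ± 0.18), which drives rather than blocks the cycle, and the retinoblastoma gene Rb1, which rose from 196 ± 43.7 to 595 ± 86.0. The inhibitor gene Cdkn2c fell 1.46-fold (adjusted p = 0.0222); its adjusted p was 0.0796 and 0.0834 without replicate 1 and replicate 2 at 33 °C and 0.159 without replicate 1 at 39 °C. The list did not pass as a whole (camera adjusted p = 0.0785), but it did without replicate 2 at 33 °C (0.0417) and after quantile normalization (0.0377). Its median was 0.10 (range -0.01 to 0.42). A second probe set of Cdkn1a showed a smaller rise, 499 ± 22.0 to 751 ± 158, whose adjusted p was 0.058 without replicate 1 at 33 °C, 0.0838 without replicate 2 at 33 °C and 0.151 without replicate 2 at 39 °C.

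More mitosis genes fell than rose at 39 °C, while as many DNA replication genes rose as fell. Of 45 tested G2/M and mitosis genes, 21 fell, 4 rose and 20 did not pass; adjusted over the list alone, 24 fell and 4 rose. The median was -0.38 (camera adjusted p = 0.000227; adjusted p = 0.238 with an estimated correlation). Without replicate 1 at 39 °C, 13 fell. The anaphase activator Cdc20 fell from 2033 ± 118 to 622 ± 43.6, securin (Pttg1) fell 2.05-fold, the mitotic kinase gene Plk1 fell 2.89-fold and cyclin B1 (Ccnb1) fell 1.92-fold. A second probe set of Ccnb1 showed a smaller fall, 2264 ± 121 to 1654 ± 25.9, or 1.37-fold. The spindle checkpoint gene Mad2l1 rose 2.04-fold and the kinetochore gene Zwint rose 1.51-fold. Other proliferation markers did not pass: Cdk1 was at 3765 ± 37.8 and 4170 ± 67.6 (adjusted p = 0.257), Mki67 at 1410 ± 629 and 984 ± 406 (0.23), and Top2a at 1582 ± 74.0 and 1304 ± 55.3 (0.072). This Top2a probe set passed with each array divided by its median (adjusted p = 0.0173). A dimmer probe set of Top2a did not pass in the main fit, at 704 ± 32.0 and 613 ± 19.0 (adjusted p = 0.236). With the replicate number as a block, which the labels do not show to pair the samples, Mki67 and the brighter Top2a probe set passed (adjusted p = 5.38e-05 and 0.027). Without replicate 1 at 33 °C the log2 change of Mki67 was -0.98, against -0.51 with all arrays.

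Of 37 tested G1/S and DNA replication genes, 8 rose, 8 fell and 21 did not pass, or 9 and 9 adjusted over the list alone, with a median of -0.01 (range -0.12 to 0.05; camera adjusted p = 0.84). The uracil glycosylase gene Ung fell 2.64-fold and the primase gene Prim1 fell 2.09-fold, whereas thymidylate synthase (Tyms) rose 2.68-fold and the histone chaperone gene Asf1b rose 1.68-fold. The helicase subunit gene Mcm2 fell from 1513 ± 97.8 to 1091 ± 134 (adjusted p = 0.0154), but its adjusted p was 0.0828 without replicate 2 at 33 °C and 0.124 without replicate 1 at 39 °C. The sliding clamp gene Pcna was at 6291 ± 301 and 7193 ± 560 (adjusted p = 0.174) and passed after quantile normalization (0.0385). Fewer genes passed when an array was left out: 4 rose and 4 fell without replicate 2 at 33 °C, 5 and 4 without replicate 1 at 39 °C, and 3 and 5 without replicate 2 at 39 °C. With each array divided by its median, 12 fell and 7 rose.

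**Figure D2:**
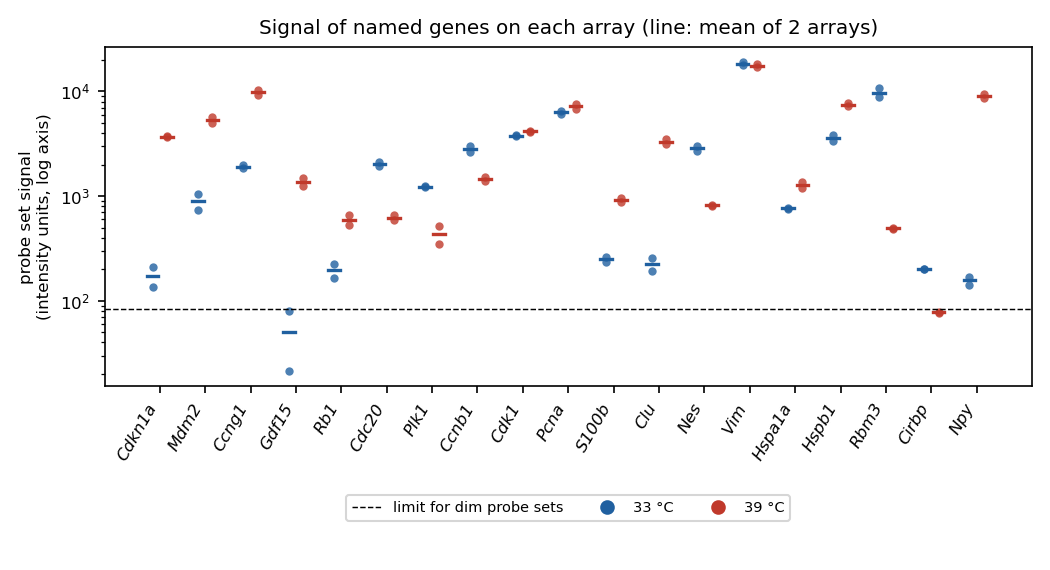
Signal of 19 genes on each of the 4 arrays, in intensity units on a log axis; points are arrays, short lines the mean of the 2 arrays at 33 °C (blue) or 39 °C (red), and the dashed line is the signal of 83.9 below which a probe set counted as dim. Cdkn1a lies at 172 and 3690 and Rbm3 at 9734 and 491, while the Cdk1, Pcna and Vim means at the 2 temperatures lie close together.

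Astrocyte markers changed unevenly. Of 57 such genes named on the array, 25 were bright enough to be tested; 11 rose, 3 fell and 11 did not pass, or 13 and 3 adjusted over the list alone. The median was 0.27 (range 0.16 to 0.33; camera adjusted p = 0.0272; adjusted p = 0.342 with an estimated correlation), and the list no longer passed without replicate 1 at 39 °C (0.0791) or with dim probe sets kept (0.106). Clusterin (Clu), a secreted chaperone, rose from 225 ± 46.2 to 3311 ± 252, the calcium-binding protein gene S100b from 249 ± 17.7 to 911 ± 58.2, cystatin C (Cst3) 2.11-fold and the hyaluronan receptor gene Cd44 1.82-fold. The glutamate transporter gene Slc1a3 rose from 163 ± 15.2 to 321 ± 33.0 (adjusted p = 0.00309); 2 further probe sets of it were dim. The intermediate filament gene Gfap was dim, at 41.1 ± 15.2 and 82.6 ± 16.5, and with no filter on dim probe sets its change of 1.04 did not pass (adjusted p = 0.193). The water channel gene Aqp4 was dim on its 3 probe sets. The brightest probe set of glutamine synthetase (Glul) was at 432 ± 7.0 and 438 ± 44.2 (adjusted p = 0.93). Its other tested probe sets did not pass in the main fit either (adjusted p = 0.095 and 0.909). The inhibitor of differentiation gene Id3 and the lipid phosphatase gene Plpp3 fell 1.28-fold and 1.47-fold. Id3 had an adjusted p of 0.0576 to 0.0958 without any 1 of the 4 arrays, with changes of -0.32 to -0.40. Plpp3 had 0.134 and 0.0787 without replicate 1 and replicate 2 at 33 °C and 0.173 without replicate 2 at 39 °C. The list's falls numbered 0 without either replicate at 33 °C and 1 without either at 39 °C, against 7 with each array divided by its median.

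Of 9 tested markers of neural progenitors and immature glia, 3 rose, 2 fell and 4 did not pass, or 4 and 2 adjusted over the list alone, with a median of 0.21 (range 0.07 to 0.32; camera adjusted p = 0.728). The intermediate filament gene nestin (Nes) fell from 2847 ± 247 to 816 ± 17.0, a log2 change of -1.80 ± 0.11, and Id1 fell 1.61-fold. The receptor gene Notch1 rose to 331 ± 4.24 from a dim signal, at least 3.94-fold, and Id2 rose 1.62-fold. Vimentin (Vim), another intermediate filament gene of glia, was at 18303 ± 827 and 17524 ± 853 (adjusted p = 0.651).

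Few markers of other brain cells were bright enough to test. Of 8 neuron markers, 2 rose (Eno2 and Vsnl1), 1 fell (Nefm, 2.48-fold) and 5 did not pass, with a median of 0.09 (range -0.02 to 0.28; camera adjusted p = 0.728); the counts were also 2 and 1 adjusted over the list alone. The Vsnl1 rise had an adjusted p of 0.0989 without replicate 2 at 33 °C, 0.113 without replicate 1 at 39 °C and 0.138 without replicate 2 at 39 °C. The only tested oligodendrocyte marker, Cnp, rose 1.55-fold, and the only microglial one, Cd14, rose from 311 ± 11.9 to 467 ± 18.0; without replicate 1 at 39 °C their adjusted p was 0.055 and 0.0724. Of 3 endothelial markers 0 passed in the limma fit, and 0 adjusted over the list alone; 1 was lower at an unadjusted p under 0.05. Ramp2, at 207 ± 13.8 and 145 ± 5.02, had an adjusted p of 0.0729 and passed with each array divided by its median (0.0333) and after quantile normalization (0.0368).

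Heat shock genes split between risers and fallers. Of 38 tested heat shock proteins and cochaperones, 16 rose, 8 fell and 14 did not pass, with the same counts of 16 and 8 adjusted over the list alone. The median was -0.01 and the mean 0.21, with a set test pointing up that did not pass (camera adjusted p = 0.252); the median ranged from -0.12 to 0.07. The HSP110 family gene Hsph1 rose 3.18-fold, heme oxygenase 1 (Hmox1) 3.19-fold and the HSP90 cochaperone gene Fkbp4 3.07-fold. The inducible HSP70 gene Hspa1a rose from 767 ± 8.91 to 1286 ± 118, and the small heat shock protein gene Hspb1 from 3618 ± 339 to 7448 ± 334. Against them, the chaperonin subunit gene Cct8 fell 2.96-fold and the HSP40 family gene Dnajb4 fell 1.43-fold. The falls numbered 4 without replicate 1 at 39 °C and 5 without each of the other arrays, and 13 with each array divided by its median. Both tested cold-inducible RNA-binding protein genes fell, over all probe sets and adjusted over the list alone: Rbm3 by 19.7-fold, and Cirbp from 200.2 ± 0.212 to a dim 77.4 ± 1.56, which is at least 2.38-fold.

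On the lists of ER stress, cholesterol synthesis and lysosomes, more genes rose than fell. Of 32 tested genes of ER stress and the unfolded protein response, 17 rose, 1 fell and 14 did not pass, or 19 and 1 adjusted over the list alone (median 0.41; camera adjusted p = 6.8e-06; adjusted p = 0.238 with an estimated correlation). The transcription factor gene Ddit3 rose from 868 ± 40.7 to 2642 ± 30.5, the disulfide isomerase gene Pdia4 rose 2.27-fold, Sdf2l1 2.22-fold and the ER chaperone gene Hsp90b1 1.98-fold. Of 21 cholesterol synthesis genes, 13 rose, 0 fell and 8 did not pass, or 15 and 0 adjusted over the list alone and also at an unadjusted p under 0.05 (median 0.59; camera adjusted p = 2.32e-06; adjusted p = 0.238 with an estimated correlation). The sterol isomerase gene Ebp rose 2.17-fold, the isopentenyl diphosphate isomerase gene Idi1 2.07-fold, lanosterol synthase (Lss) 2.22-fold and the methylsterol oxidase gene Msmo1 2.11-fold. Of 39 lysosome genes, 19 rose, 0 fell and 20 did not pass, or 21 and 0 adjusted over the list alone and 23 and 0 at an unadjusted p under 0.05 (median 0.37; camera adjusted p = 6.8e-06; adjusted p = 0.238 with an estimated correlation). The hexosaminidase gene Hexa went from 1003 ± 44.5 to 2925 ± 245, and the protease genes Tpp1, Ctsd and Ctsa rose 2.75-fold, 2.51-fold and 1.92-fold. Without replicate 1 at 39 °C, 12 lysosome genes rose and 1 fell, and 14 rose and 2 fell with each array divided by its median.

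Among secreted factors of the senescence-associated kind and interferon response genes, risers also outnumbered fallers. Of 22 tested secreted factors, 14 rose, 3 fell and 5 did not pass, with the same counts of 14 and 3 adjusted over the list alone (median 0.77; camera adjusted p = 5.18e-05; adjusted p = 0.238 with an estimated correlation). The chemokine gene Ccl2 rose from 552 ± 36.0 to 3338 ± 3.04, the chemokine gene Cxcl10 from 156 ± 33.5 to 1631 ± 138, interleukin 6 (Il6) from 110.1 ± 3.39 to 539 ± 20.8, and the growth factor binding protein gene Igfbp2 rose 5.21-fold. Of 19 interferon response genes, 10 rose, 0 fell and 9 did not pass, or 11 and 0 adjusted over the list alone and also at an unadjusted p under 0.05 (median 0.87; camera adjusted p = 7.89e-06; adjusted p = 0.238 with an estimated correlation). Besides Cxcl10 these included the membrane protein gene Ifitm3, which rose 2.66-fold, and the peptide transporter gene Tap1, which rose 3.56-fold and is also on the p53 list. The class I histocompatibility gene RT1-CE5 went from a dim 38 ± 0.849 to 768 ± 108, at least 9.14-fold, but belongs to a family of near-identical genes whose transcripts its probes could share, so which member rose is uncertain.

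More genes of the actin and contractile cytoskeleton fell than rose. Of 26 tested, 19 fell, 1 rose and 6 did not pass, or 20 and 1 adjusted over the list alone (median -0.54; camera adjusted p = 3.2e-07; adjusted p = 0.238 with an estimated correlation). Smooth muscle actin (Acta2) fell from 7587 ± 165 to 3306 ± 102, the tropomyosin genes Tpm1 and Tpm2 fell 2.19-fold and 1.94-fold, and the actin-associated gene Pdlim7 fell 2.59-fold. The 3′ to 5′ signal ratio of the beta-actin control probe sets, a sign of RNA quality, was 1.39 ± 0.0318 at 33 °C and 1.70 ± 0.188 at 39 °C, and that of GAPDH was 1.08 ± 0.000507 and 0.999 ± 0.0232. Markers of pericytes and smooth muscle, some of them on the same list, fell for 3 of 8 tested genes, rose for 1 and did not pass for 4, with 3 and 1 adjusted over the list alone (median -0.25, range -0.46 to -0.25; camera adjusted p = 0.211). The fallers were Acta2, Cnn1 and Mcam, and numbered 1 without replicate 2 at 33 °C or replicate 1 at 39 °C. The smooth muscle myosin gene Myh11 rose from a dim signal, at least 1.68-fold, but its adjusted p was 0.0889 without replicate 2 at 33 °C, 0.135 without replicate 1 at 39 °C and 0.0866 without replicate 2 at 39 °C.

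Of 52 tested extracellular matrix genes, 15 fell, 10 rose and 27 did not pass, or 17 and 11 adjusted over the list alone (median -0.06, range -0.17 to -0.005; camera adjusted p = 0.356). The lysyl oxidase genes Loxl1 and Lox fell 2.33-fold and 1.92-fold and the protease inhibitor gene Timp1 fell 1.76-fold, whereas the proteoglycan gene biglycan (Bgn) rose 1.70-fold. Without replicate 1 at 39 °C, 6 rose. Of 12 markers of fibroblasts and meninges, 3 fell, 2 rose and 7 did not pass, or 4 and 3 adjusted over the list alone (median -0.17, range -0.28 to -0.08; camera adjusted p = 0.564). The calcium-binding protein gene S100a4 fell from 4758 ± 57.6 to 1276 ± 36.6, the retinoic acid synthesis gene Aldh1a2 fell 2.49-fold, and the proteoglycan gene osteoglycin (Ogn) fell at least 3.65-fold to a dim signal. Igfbp2, also among the secreted factors, rose.

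**Figure D3:**
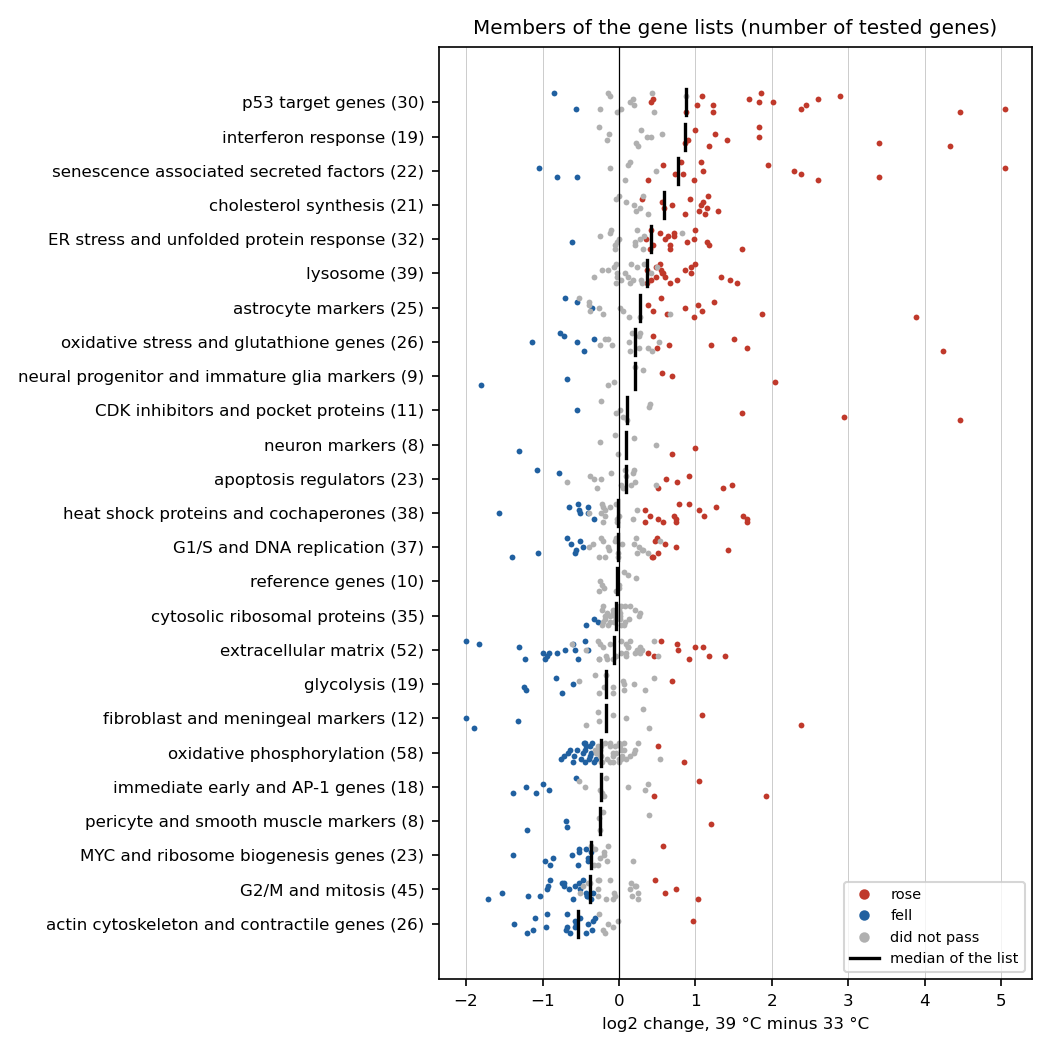
Log2 change at 39 °C against 33 °C (horizontal axis) of each tested gene of the 25 lists with at least 5 tested genes, 1 point per gene, red for genes that rose, blue for those that fell and grey for those that did not pass; black bars are list medians and numbers in brackets count tested genes. Medians run from -0.54 for contractile genes to 0.88 for p53 targets; those within 0.12 of 0, such as heat shock proteins at -0.01, change sign or size with the scaling of the arrays.

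More ribosome biogenesis and oxidative phosphorylation genes fell than rose, although most tested oxidative phosphorylation genes did not pass. Of 23 tested MYC and ribosome biogenesis genes, 12 fell, 1 rose and 10 did not pass, or 13 and 1 adjusted over the list alone (median -0.36; camera adjusted p = 0.000139; adjusted p = 0.238 with an estimated correlation). The nucleolar genes Fbl, Ebna1bp2 and Dkc1 fell 1.87-fold, 1.95-fold and 1.82-fold, and spermidine synthase (Srm) fell 1.53-fold. The falls numbered 7 without replicate 1 at 33 °C and 7 without either replicate at 39 °C, and 2 rose after quantile normalization. Of 58 oxidative phosphorylation genes, 21 fell, 2 rose and 35 did not pass, with 21 and 2 adjusted over the list alone (median -0.23; camera adjusted p = 0.000529; adjusted p = 0.342 with an estimated correlation). The respiratory complex I genes Ndufv2 and Ndufb10 fell 1.70-fold and 1.64-fold and the ATP synthase gene Atp5f1a fell 1.59-fold, while the complex I gene Ndufb2 rose 1.80-fold. The falls numbered 7 without replicate 2 at 39 °C, 12 without replicate 1 at 33 °C and 13 without replicate 1 at 39 °C. Of 19 glycolysis genes, 5 fell, 1 rose and 13 did not pass, with 5 and 1 adjusted over the list alone (median -0.17, range -0.28 to -0.12; camera adjusted p = 0.115); Tpi1 and Eno1 fell 1.68-fold and 1.52-fold, and the lactate transporter gene Slc16a3 and the kinase gene Pdk1 fell 2.33-fold and 2.36-fold. With each array divided by its median, 8 glycolysis genes fell. Of 35 cytosolic ribosomal protein genes, 3 fell (Rpl21, Rpl11 and Rpl14, by 1.35-fold, 1.21-fold and 1.25-fold), 0 rose and 32 did not pass, with 0 either way adjusted over the list alone, and 4 lower and 2 higher at an unadjusted p under 0.05 (median -0.04, range -0.15 to 0.02; camera adjusted p = 0.308). The list passed, toward lower signals, without replicate 1 at 39 °C (adjusted p = 0.0401). The falls of ribosomal protein genes numbered 0 without replicate 1 at 33 °C or replicate 2 at 39 °C, 1 without either other array and 7 with each array divided by its median.

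The remaining stress lists moved both ways. Of 18 immediate early and AP-1 genes, 6 fell, 3 rose and 9 did not pass, or 7 and 4 adjusted over the list alone (median -0.23, range -0.35 to -0.12; camera adjusted p = 0.203); the AP-1 subunit gene Fosl1 rose from 181 ± 0.849 to 684 ± 71.9, and Klf2, Egr1 and Egr2 fell 2.13-fold, 1.88-fold and 2.32-fold. Of 26 oxidative stress and glutathione genes, 7 rose, 6 fell and 13 did not pass, with 7 and 6 adjusted over the list alone (median 0.21, range 0.10 to 0.34; camera adjusted p = 0.252). Ephx1 rose from 174 ± 4.53 to 3301 ± 108 and the transcription factor gene Nfe2l2 rose 2.31-fold, while the glutathione transferase gene Gstp1 fell 2.20-fold; 2 fell without replicate 1 at 39 °C and 4 rose without replicate 2 at 39 °C. Of 23 apoptosis regulators, 6 rose, 2 fell and 15 did not pass, or 7 and 2 adjusted over the list alone (median 0.09, range -0.02 to 0.16; camera adjusted p = 0.308). The survival gene Bcl2l1 rose 2.58-fold, Pdcd4 2.79-fold, Diablo 1.69-fold and Bnip3l 1.53-fold; 1 gene fell when any single array was left out, and 4 with each array divided by its median.

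Among the 12 genes with the largest fitted rises, those not yet given were phospholamban (Pln), the sodium channel gene Scn7a, Spetex2l2, the DNA repair gene Mgmt and the fatty acid transport protein gene Slc27a3. Mgmt went from 357 ± 29.1 to 3844 ± 524 and Slc27a3 from 179 ± 2.19 to 1689 ± 175. Pln, Scn7a and Spetex2l2 were dim at 33 °C and rose at least 6.44-fold, 6.79-fold and 3.87-fold, so their places among the 12 are not settled; Spetex2l2 is one of a family of similar genes, so its identity is uncertain. Among the 12 largest fitted falls, the calcium-binding protein gene S100a16 went from 580.4 ± 5.94 to a dim 67.8 ± 11.7, at least 6.91-fold, the anaphase-promoting complex gene Anapc1 fell 3.96-fold and the myelin protein gene Pmp22 went from 7677 ± 512 to 2343 ± 20.1. Nrep, C1h19orf33 and the small GTPase gene Arf2 fell 3.60-fold, 3.49-fold and 3.28-fold. The collagen gene Col5a3 and the RNA-binding protein gene Rbpms fell to dim signals, at least 2.50-fold and 2.44-fold, which leaves their places unsettled too; Col5a3 had an adjusted p of 0.0604 without replicate 1 at 33 °C.

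Of 10 tested reference genes, 0 passed in the limma fit and 0 adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (median -0.02, range -0.13 to -0.004; camera adjusted p = 0.549). Pgk1, Tfrc, Gusb and Ywhaz came nearest, with adjusted p of 0.0748, 0.156, 0.159 and 0.161, and these 4 fell with each array divided by its median. The 3 GAPDH control probe sets, which were not tested, read 15715 ± 40.0, 14495 ± 43.7 and 15204 ± 1662 at 33 °C and 12757 ± 199, 12781 ± 496 and 12967 ± 1330 at 39 °C. The beta-actin control probe sets, not tested either, were also lower at 39 °C, with log2 changes of -0.25 (3′), -0.54 (5′) and -0.28 (middle). Of 953 genes with several tested probe sets, 15 had probe sets that changed in opposite directions, which included no gene named here.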

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

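The tests in this part were chosen after the result was seen, except those of measurement precision, of the scaling and of dim probe sets, which were fixed before their results were known.

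The poly-A spike-in controls, bacterial transcripts of the kind added to RNA before labelling, were not part of any comparison and drew attention because they differed between the temperatures. Their mean log2 signal over 24 probe sets was 0.513 higher at 39 °C (1.43-fold), with 22 of 24 probe sets higher. Brighter hybridization or scanning should raise the hybridization controls as much; these rose by 0.0867 over 18 probe sets, 0.427 less. A first bound, 2 standard errors over probe sets (0.0547 and 0.0291), had spoken against this explanation; after that result was seen it was replaced by a bound on the spread between arrays, because probe sets of one array are not independent. Over arrays the SE was 0.204, with differences of 0.226 and 0.628 at 39 °C against -0.0329 and 0.0329 at 33 °C. By that bound the explanation stays open. A brightening equal for all probe sets would, however, have been divided out when the arrays were scaled to a common mean. It therefore cannot have raised the spike-ins, and only a brightening that differed between probe sets stays open. A smaller share of polyadenylated RNA in the total RNA at 39 °C may also raise spike-ins relative to cell transcripts. The shift of 0.513 is of that direction, but no polyadenylated RNA was measured and the amounts added are not stated, so this and uneven spiking cannot be told apart.

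The 3′ to 5′ ratio of the beta-actin control probe sets, also outside the comparisons, was 1.705 ± 0.188 at 39 °C (1.84 and 1.57) against 1.392 ± 0.0318 at 33 °C (1.42 and 1.37), whereas that of GAPDH was 0.999 ± 0.0232 against 1.08 ± 0.000507.

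Mitosis genes fell as a list (camera adjusted p = 0.000227; adjusted p = 0.238 with an estimated correlation), whereas the DNA replication list did not pass (0.84). The mean log2 change was -0.35 ± 0.08 (SE over 44 genes on the mitosis list alone) and -0.03 ± 0.09 (36 genes on the replication list alone). Lower precision for replication genes is argued against: their median SE was 0.133 against 0.117 for mitosis genes, a ratio of 1.14, where at least 1.5 had been set as needed to hide such a fall. A chance draw of 2 lists stays open. The difference was -0.325, with a two-sided permutation p of 0.00843 over 100000 reassignments of genes, but that test takes genes as independent. With the correlation estimated the mitosis list did not pass, but that test has little power with so few arrays and cannot decide. The change of temperature and large T antigen stays open too, and was not tested as an explanation.

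Of the probe sets that changed by 2-fold or more, 68.5% were rises. Noise of dim probe sets is argued against, since the share was 67.4% with probe sets below the 60th percentile left out. The scaling of the arrays may account for the excess: with each array divided by its median the share was 53.3%, and after quantile normalization 61.1%. Which scaling is nearer to the amounts per cell is not known from these arrays.

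The 4 arrays can be split into pairs in 3 ways, and 1 of the 3, the real one, gave as many as 3161 changed probe sets; the highest other split gave 0 in the limma fit. Each other split mixes the temperatures within its pairs, so their difference adds to the spread and makes calls unlikely in advance. The 0 calls therefore do not measure how many would arise by chance, and the splits are too few for a share under 0.05.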

How the results depend on the processing

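All alternatives were planned. The 3161 changed probe sets became 1821 to 2342 with 1 array left out, where fewer samples carry the fit, and stayed within 1.5 times otherwise; the 669 changed by 2-fold or more became 368 with the filter at the 60th percentile, where fewer are tested. In every alternative, 0 of the probe sets called both there and in the main fit changed direction. Probe sets that lost their call were not counted. The filters, the eBayes options and the replicate block leave the fitted changes as they were, so no reversal was possible there. Of 141 named probe sets, 115 kept direction and side of the threshold in every alternative that tested them; the filter at the 60th percentile tested 111. The 11 called lists became 0 with an estimated correlation, which has little power with so few arrays (adjusted p = 0.238 for p53 targets and for mitosis, 0.342 for astrocyte markers). They became 20 with fry, which does not compare a list with other genes: CDK inhibitors 0.0126, progenitor markers 0.0059, heat shock proteins 0.01. CDK inhibitors (main 0.0785) passed after quantile normalization (0.0377) and ran from 0.0417 to 0.215 with 1 array left out. Astrocyte markers (main 0.0272) had 0.106 without the dim filter and 0.0158 to 0.0791 with 1 array left out. The cause was not tested for the lists. The labels do not say whether replicate numbers pair the samples. The replicate differences of the 2 temperatures correlated at 0.133 across probe sets, which does not settle it with so few arrays. A replicate block gave 4231 changed probe sets and an adjusted p of 4.53e-05 for CDK inhibitors and 0.0413 for oxidative stress genes (main 0.252). With it, 6 named probe sets that had not passed did so, among them that of Mki67 (5.38e-05) and the brighter of Top2a (0.027). The arrays give no background level, so changes of probe sets below a signal of 83.9 could not be separated from noise.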

Other observations

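The gene families in this part were looked at after the data had been seen. Among genes whose symbols start with Eif, mostly translation initiation factors and their kinases and binding proteins, more fell than rose. Among 214 families of at least 5 tested genes sharing a symbol stem, the Eif genes were the only one past the threshold for an excess of falls, and 0 families passed for an excess of rises (Fisher's exact test, one-sided, adjusted over both directions, which takes genes as independent). Of 45 tested Eif genes, 19 fell, 5 rose and 21 did not pass (exact p = 2.86e-05, adjusted p = 0.0123). Their median log2 change was -0.26 as deposited, -0.37 with each array divided by its median and -0.25 after quantile normalization. Eif5a, an elongation and termination factor despite its name, had a signal of 7579 ± 449 at 33 °C and 4486 ± 113 at 39 °C, and the eIF3 subunit genes Eif3i and Eif3d had 4896 ± 801 and 3119 ± 16 at 33 °C against 2859 ± 172 and 1864 ± 6.36 at 39 °C. The helicase gene Eif4a2 rose from 2722 ± 86.5 to 5382 ± 204, whereas its paralog Eif4a1 was at 7576 ± 1210 and 5834 ± 643 (adjusted p = 0.0496). The interferon-induced kinase gene Eif2ak2 rose from 227 ± 57.1 to 498 ± 38.2. The falls numbered 12 without replicate 1 at 33 °C and 11 without replicate 1 at 39 °C, and the rises 2 without replicate 2 at 39 °C.

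Genes of the S100 calcium-binding proteins moved apart: of 8 tested, 4 fell (S100a4, S100a6, S100a13 and S100a16), 1 rose (S100b) and 3 did not pass, and under each scaling S100b was the only riser. S100a6 went from 13290 ± 535 to 8232 ± 285. Rat class I and II histocompatibility genes (RT1) also went both ways: of 10 tested, 3 rose, 2 fell and 5 did not pass, the same counts under each scaling, while 2 rose and 1 fell without replicate 2 at 39 °C. RT1-M3-1 rose from 171 ± 19.7 to 709 ± 21.2 and RT1-CE12 fell from 920 ± 26.0 to 529 ± 14. Members of this family are similar enough in sequence that a probe set can read several of them.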
